A study of Mus musculus with 36 samples.

How the data were processed

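Gene expression was measured by RNA sequencing in 36 libraries of B cells sorted from mouse spleen (strain Balb/c). Cells were sorted by flow cytometry, libraries were made with the SMART-Seq v4 low-input kit followed by Nextera tagmentation, and paired reads were sequenced on NovaSeq or NextSeq instruments, per the labels' protocols. The labels say that some libraries had longer reads than the others, without saying which. Per the submitters' processing notes, the tools were FastQC 0.11.5, cutadapt 1.8.3, STAR 2.6.0c, featureCounts from Subread 1.6.2 and limma, and the genome build was mm10. The annotation, the strand setting, the normalization method and the order of the steps are not given in the sources used here.

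The deposited files hold log2 values, 1 column per library, for the same 23420 genes in the same order. Taken back to the linear scale, the libraries sum to 0.9793 to 1.0596 times the fixed total of CPM values, so the values lie close to a log2 CPM scale. The deposited values are not counts, so the sequencing depth of each library is unknown, and no counting interval or limit of detection is given. As a stand-in for depth, the number of genes above their lowest value ranged from 10056 to 12787 per library. The lowest value of a gene was shared by several libraries of each replicate number in 11725 genes. It was identical in the 3 replicate numbers for 5810 of them, which hold the same value in all libraries. It differed by number for the remaining 5915. The lowest value thus depended on the replicate number in every one of these genes that varied. No label describes a step that would do this. The table holds 0 immunoglobulin constant or variable genes and 0 mitochondrially encoded genes. Library construction did not mark strand in any way the labels describe, so overlapping and antisense genes, and near-identical gene copies, cannot be told apart here.

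Libraries were grouped by their labels into 14 groups, 8 of 3 libraries and 6 of 2. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries, which may in part be technical. The tests planned before the data were examined assumed counts; since the values are log2 values, limma 3.58.1 (R 4.3.3, statmod 1.5.0) was used in their place. Each comparison came from 1 linear model over all 36 libraries with a mean per group and 22 residual degrees of freedom, with a mean-variance trend and robust moderation. Genes with a log2 value of at least 0 in at least 2 libraries were tested, which left 11826. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison, and an adjusted p under 0.05 was the threshold. All adjusted p-values for genes below are from limma. A log2 fold change is the mean of the first group minus the mean of the second, given with its standard error (SE), and combined groups weight each subset equally. Fold changes of genes near the lowest value depend on how the deposited values treat absent reads and are uncertain in size.

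Of 30 gene lists written before the data were examined, 28 had enough measured genes to be tested with camera, using its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The 448 tests of a list in a comparison gave 138 past the threshold, and 61 with a correlation estimated from the data. Calls that were lost with the estimated correlation are given with that p. Genes are named by a rule also fixed beforehand. Cd80 and Pdcd1lg2, which encode the markers in the subset names, come first. Then come the 8 largest increases and 8 largest decreases (5 and 5 in the minor comparisons) among genes past the threshold, with a mean log2 value of at least 3 and no overlap between the sides, leaving out clone names, pseudogenes and variable segments. Up to 4 genes with the smallest p per list follow, and Bcl6, Prdm1, Bach2, Klf2, Zbtb32, Myc and Mki67, with others, could be named anywhere. Some genes that the rule names are not reported here.

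Signature scores are the mean log2 value of the genes higher in a defining comparison minus the mean of those lower, both with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Score differences between groups were tested with two-sided exact permutation tests in scipy 1.17.1. Gene positions come from the RefSeq table of GRCm38.p6, the assembly that mm10 represents; 21571 table symbols matched directly, 1688 by an older symbol and 161 not at all.

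Replicate numbers were checked for pairing by correlating each library's deviations from its group mean. Within the week 10 groups all 18 same-number pairs correlated above 0.1 (0.215 to 0.574), and so did the 3 pairs of the day 14 groups (0.374 to 0.56), so the numbers were taken to pair those libraries. Day 0 FO libraries also correlated above 0.1 with every same-number week 10 library (12 pairs, 0.164 to 0.478) and GL7 PreC library (3 pairs, 0.144 to 0.329), so they were taken as paired with these. PreC and day 14 libraries (6 pairs, from -0.028) and day 14 and week 10 libraries (24 pairs, from -0.064) were not. This evidence comes from the values, not from the labels, and an adjustment by replicate number could itself leave such a correlation. Day 0 FO replicate 1 carried Y-linked Ddx3y at 5.06, against -4.0 in the week 10 and PreC libraries numbered 1. A shared number was thus not a shared mouse there. For the paired libraries, blocked values are given beside the result where they change a call or move a count by more than 1.5 times. The main fit counts paired libraries as separate, so SEs may be too small where the GC or the memory groups are combined.

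The limma step was tested on simulated data. The noise was normal, independent between libraries and between genes, with a single SD per gene. Unequal library quality and the correlation of same-number libraries were not simulated, so the shares below hold for that setting only. For week 10 DP versus DN it recovered 59% of genes changed by a log2 of 1 and 90% of those changed by 2, with 3.2% of calls false; for week 4 DP versus DN after FGK, 46% and 77%, with 2.4% false; for week 4 NP-Ficoll versus FGK, 84% and 100%, with 6.6% false, more than the threshold of 0.05 allows. Alternatives were other filters on low values, only the libraries compared, a replicate block and each library left out. Chosen after seeing the data were pseudocounts of 1 and 0.5, median centring, library quality weights, the omission of libraries numbered 3 and a myeloid marker covariate. That covariate was the centred mean of 10 myeloid list genes, without Mpeg1, Ms4a7 and Mpo. Week 4 DP FGK replicate 1, with Mpo at 9.48, scored 0.057 on it, so it does not adjust for every myeloid signal. The weights first came from limma's default method, which did not converge and gave erratic counts. The gene-by-gene method was then used. It gave replicate 1 the largest weight in each week 10 group (from 3.499 in CD80SP to 8.435 in PDL2SP). Weighted counts of week 10 thus rest largely on 1 library per group. Count-based alternatives, and 1 without immunoglobulin genes, could not be run on these values. Where the number of list members adjusted over the list alone is not given, it equalled the number over all tested genes.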

Results

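The series measured transcript levels in splenic B cell subsets of mice. Day 0 cells labelled FO, an abbreviation in wide use for follicular B cells, came from B18+/- JK-/- mice. Cells of a Balb/c transfer system were sorted on day 2.5 as GL7 PreC, on day 14 as germinal center (GC) cells of the dark zone (DZ) and light zone (LZ), and at week 10 as subsets labelled DN, PDL2SP, CD80SP and DP. Each of these 8 groups had 3 libraries. The week 10 CD80SP libraries were deposited apart from the other week 10 libraries, together with those of week 4, so any batch would coincide with that subset. Memory subsets DN, CD80SP and DP were also sorted at week 4 after NP-Ficoll (NPFic) or under the label FGK, with 2 libraries per group. The column headers of the 12 week 4 libraries carry GK15, which the labels do not explain. Whatever it marks would coincide with week 4. Values are deposited log2 values on a scale close to CPM, and group values are mean ± SD. The depth of each library is unknown. Per the series' design text, differences between DN and DP cells, and differences involving GC cells, served to place putative precursors; the EMP cells it also names are not analysed here. All week 10 libraries carry the label NPCGG. FGK, NPCGG and PreC are not spelled out in the labels.

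At week 10, DP cells had 192 genes higher and 119 lower than DN cells. Cd80 (GRCm38 chromosome 16, 38457430 to 38495958), which encodes a costimulatory ligand, stood at 3.76 ± 0.35 in DP and -1.75 ± 1.15 in DN (n = 3 each), a log2 fold change of 5.52 ± 0.59 (SE). Pdcd1lg2 (chromosome 19, 29410919 to 29472927), which encodes PD-L2, stood at 6.84 ± 0.41 and 4.46 ± 0.49, a log2 fold change of 2.39 ± 0.34. Both genes encode sort markers, so their difference checks the labels. Among genes with a mean log2 value of at least 3 and no overlap between DP and DN libraries, large increases included Sema4f (4.73 ± 1.03), Gpr82 (4.35 ± 0.71), the signaling adaptor gene Lcp2 (3.68 ± 0.55), S100a6 (3.02 ± 0.54), the protease inhibitor gene Slpi (2.72 ± 0.75), the transcription factor gene Bhlhe41 (2.48 ± 0.56), Myadm (2.47 ± 0.33) and Anxa2 (2.40 ± 0.30). Large decreases under the same limits included Edaradd (-2.29 ± 0.50), the potassium channel gene Kcnk13 (-1.96 ± 0.44), Fam189b (-1.94 ± 0.52), the Wnt secretion factor gene Wls (-1.87 ± 0.43), Rasgef1b (-1.81 ± 0.23), Lpar6 (-1.78 ± 0.27), Sla (-1.73 ± 0.21) and Stom (-1.68 ± 0.42).

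Among 16 genes of the GC B cell core list, 5 rose and 1 fell in DP (camera adjusted p = 1.54e-06); adjusted over the list alone, 8 rose and 2 fell. Basp1 (5.67), Gcsam (3.39), Plxnb2 (2.14) and Neil1 (1.83) rose, while Bcl6 (chromosome 16, 23965050 to 23988866), the GC transcription factor gene, fell by 0.97. Of 16 memory-associated genes, 4 rose and 0 fell (5 and 1 adjusted over the list alone, and 5 and 1 with the replicate block; adjusted p = 5.18e-05): Zbtb32 (2.85), Vim (1.69), Cd44 (1.16) and the integrin gene Itgb1 (1.07). Of 17 naive and quiescence genes, 4 fell and 0 rose (6 fell adjusted over the list alone, adjusted p = 4.11e-06), among them Satb1 (-1.58), Foxp1 (-0.98) and Cd55 (-0.77). The 18 type I interferon genes had a median of -0.54, with 1 fallen (Rtp4, -1.15), 2 with the replicate block and 3 adjusted over the list alone (list adjusted p = 8.21e-05). The 12 pan B cell markers had a median of -0.22, with 1 fallen (adjusted p = 0.00154, and adjusted p = 0.14 with an estimated correlation). Of 8 T cell markers, Tcf7 (5.21) and Lck (0.72) rose, and 3 adjusted over the list alone (list adjusted p = 0.0377, and adjusted p = 0.333 with an estimated correlation). Library quality weights gave 1143 genes, and the fit without the 8 libraries numbered 3 gave 122; leaving out 1 library gave 180 (DP replicate 2), 183 (DN replicate 3) and 205 (DP replicate 1).

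**Figure D1:**
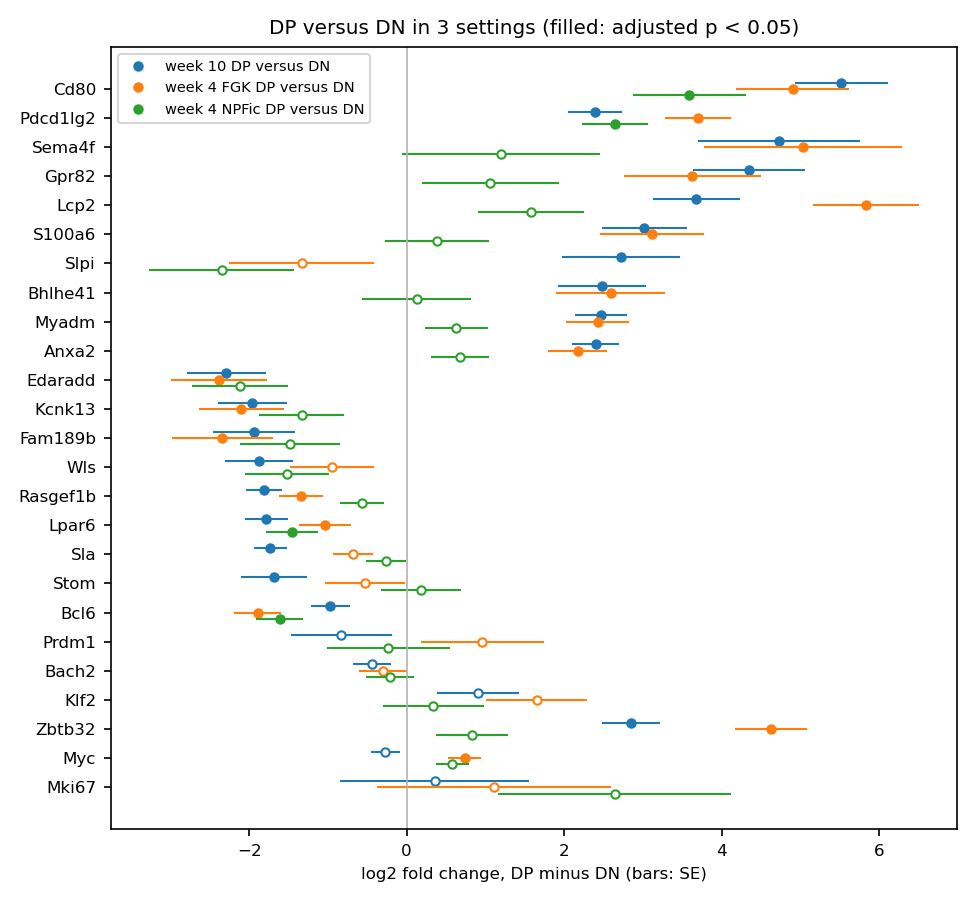
Log2 fold change of DP minus DN (x axis; points, bars are SE) for the named genes (y axis) at week 10 and at week 4 after FGK and NPFic; filled points have an adjusted p under 0.05. Cd80 lies at 5.52, 4.90 and 3.59 in the 3 settings, and Bcl6 below 0 in each.

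The single-marker subsets were compared with DN and with DP. PDL2SP cells differed from DN cells in 2 genes, Pdcd1lg2 (2.06 ± 0.34) and the potassium channel gene Kcnn4 (1.07 ± 0.19); 270 genes had an unadjusted p under 0.05, and 4 passed with the replicate block and 246 with library quality weights. By limma, 1 gene passed without DN replicate 2 and 1 without DN replicate 3, and 0 passed without PDL2SP replicate 1 (275 at an unadjusted p under 0.05) or PDL2SP replicate 2 (135). The GC core list moved up in PDL2SP, with a median of 0.52 (adjusted p = 8.15e-06), and 5 members rose when adjusted over the list alone. CD80SP cells had 149 genes higher and 120 lower than DN, with Slpi (3.88 ± 0.75), S100a6 (3.55 ± 0.54), Gpr82 (3.50 ± 0.71), Lcp2 (2.98 ± 0.55) and Bhlhe41 (2.93 ± 0.56) among those higher. Cd80 was higher by 5.10 ± 0.59 and Pdcd1lg2 by 0.07 ± 0.34, the latter not past the threshold. The ubiquitin ligase gene Neurl3 (-2.04 ± 0.36), Skap1 (-2.02 ± 0.51), Trafd1 (-1.53 ± 0.36), Csrnp1 (-1.49 ± 0.26) and Sufu (-1.47 ± 0.34) fell. Of the 17 naive and quiescence genes 5 fell (8 adjusted over the list alone, and 8 with the replicate block; adjusted p = 7.09e-07), among them Fcer2a (-1.07), which encodes CD23. Zbtb32 rose by 3.05, while Bcl6 fell by 1.21. The count became 1348 with the replicate block, 74 in a fit of only the libraries compared and 4133 with library quality weights, and median centring gave 141 higher and 144 lower. Without 1 library it was 68 (DN replicate 3), 86 (DN replicate 1), 82, 73 and 1202 (CD80SP replicates 1, 2 and 3).

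DP cells differed from PDL2SP cells in 113 genes (200 with the replicate block), with Tox (4.01 ± 0.65), Parm1 (3.52 ± 0.87), S100a6 (2.47 ± 0.54), Zbtb20 (2.10 ± 0.38) and Spn (1.88 ± 0.38) higher. Blvrb (-1.48 ± 0.19), Bcl9 (-1.41 ± 0.32), Lpar6 (-1.40 ± 0.27), Rasgef1b (-1.35 ± 0.23) and Stat4 (-1.34 ± 0.25) were lower. Cd80 differed by 4.07 ± 0.59 and Pdcd1lg2 by 0.32 ± 0.34, the latter not past the threshold. DP and CD80SP cells differed in 190 genes (1098 with the replicate block), among them Pdcd1lg2 (2.31 ± 0.34), Dtx2 (1.90 ± 0.44), Trafd1 (1.87 ± 0.36), Vps52 (1.86 ± 0.45) and Ppme1 (1.77 ± 0.36). Ly6c2 (-2.72 ± 0.62), Stx3 (-2.63 ± 0.61), Wls (-2.23 ± 0.43), Bcl9 (-1.50 ± 0.32) and Ms4a7 (-1.49 ± 0.34) were lower in DP. The GC core list was higher in DP than in CD80SP (3 of 16 rose, 7 adjusted over the list alone and 5 with the replicate block, adjusted p = 0.000183), with Gcsam at 3.74 and the migration receptor gene S1pr2 at 1.51. The B-1 and marginal zone list was lower (2 of 13 fell, 4 adjusted over the list alone, adjusted p = 0.000727), with Cd9 at -1.38 and Cd36 at -1.26. CD80SP and PDL2SP cells differed in 56 genes (86 with the replicate block). Slpi (3.49 ± 0.75), Ly6c2 (3.07 ± 0.62), S100a6 (3.00 ± 0.54), Zbtb32 (2.52 ± 0.37) and Bhlhe41 (2.40 ± 0.56; adjusted p = 0.054 with the block) were higher in CD80SP, and Neurl3 (-1.89 ± 0.36), Csrnp1 (-1.18 ± 0.26), Il4ra (-0.95 ± 0.21) and Pxk (-0.92 ± 0.17) lower. Without 1 library, DP versus PDL2SP gave 69, 65 and 75 (DP replicates 1, 2 and 3) and 66 (PDL2SP replicate 2), and DP versus CD80SP gave 37, 66 and 25 (DP replicates 1, 2 and 3) and 27, 22 and 865 (CD80SP replicates 1, 2 and 3). CD80SP versus PDL2SP gave 27, 98 and 29 (PDL2SP replicates 1, 2 and 3) and 32 and 25 (CD80SP replicates 1 and 2). Fits of only the libraries compared gave 50, 27 and 5 genes for DP versus PDL2SP, DP versus CD80SP and CD80SP versus PDL2SP. Library quality weights gave 1354, 3812 (1862 higher, 1950 lower) and 3236 (1616 higher, 1620 lower). Replicate 1 had the largest weight in each of these subsets (in PDL2SP 8.435 against 0.399 and 0.547). The weighted counts thus rest largely on 1 library per subset.

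In day 14 GC cells, 380 genes were higher and 107 lower in LZ than in DZ. Large increases, again among genes with a mean log2 value of at least 3 and no overlap, included Serpinb1a (2.99 ± 0.12), the cyclin gene Ccnd2 (2.94 ± 0.27), the sterol transporter gene Abcg1 (2.77 ± 0.21), Aldoc (2.64 ± 0.38), the transcription factor gene Hhex (2.62 ± 0.17), Cfp (2.50 ± 0.15), Ephx1 (2.27 ± 0.16) and the migration receptor gene Gpr183 (2.12 ± 0.19). Large decreases under these limits included Ptgr1 (-1.89 ± 0.44), Sepp1 (-1.72 ± 0.31), Pafah1b3 (-1.69 ± 0.19), Arl5c (-1.38 ± 0.25), Otub2 (-1.36 ± 0.32), Pfn2 (-1.27 ± 0.32), Lmo4 (-1.27 ± 0.25) and Cdc14b (-1.21 ± 0.34). The light zone list rose in 10 of 19 genes with 0 falling (14 adjusted over the list alone; adjusted p = 1.66e-27), including Cd83 (1.93), Fcer2a (2.07), Cd40 (1.32) and Cd86 (1.36). Of 16 NF-kB targets 9 rose (12 adjusted over the list alone, adjusted p = 1.06e-19), including Nfkbia (1.44) and Birc3 (1.16). MHC class II presentation rose in 6 of 11 (10 adjusted over the list alone, and 10 with the replicate block; adjusted p = 5.87e-17), including H2-Oa (1.39), H2-DMa (0.94) and Ctss (0.79), and 6 of 16 memory-associated genes rose (10 adjusted over the list alone, adjusted p = 1.22e-13), including Ccr6 (4.95) and Bcl2 (2.67). The dark zone list had 1 of 10 past the threshold, Lmo4, and 2 adjusted over the list alone, with a median of -0.54 (adjusted p = 0.00199). S phase genes had a median of -0.41, with Mcm2 (-0.68) and Mcm6 (-0.62) falling and 3 adjusted over the list alone (adjusted p = 3.28e-05, and adjusted p = 0.109 with an estimated correlation). Oxidative phosphorylation genes fell in 3 of 17 (7 adjusted over the list alone, adjusted p = 1.42e-07), including Atp5b (-0.55). Bcl6 (6.60 ± 0.27 and 6.57 ± 0.08) did not pass the threshold. A fit of only these 6 libraries gave 61 genes in place of 487, and leaving out DZ replicate 1 gave 318.

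Day 2.5 GL7 PreC cells differed from day 0 FO cells in 5838 genes, 2649 higher and 3189 lower. All 20 G2/M genes rose (adjusted p = 1.06e-19) and all 18 S phase genes rose (adjusted p = 3.27e-20). The mitotic kinase gene Plk1 rose by 8.93 ± 1.16, Ccnb2 by 8.11 ± 0.84, Tpx2 by 8.02 ± 0.70, Ccna2 by 8.01 ± 0.45, Birc5 by 7.89 ± 0.44, Bub1b by 7.31 ± 0.78, Nusap1 by 7.30 ± 0.41 and Top2a by 7.23 ± 0.47. Mki67 stood at 6.93 ± 1.00 in PreC and -4.57 ± 1.21 in FO (n = 3 each). Large decreases, at a mean log2 value of at least 3 and without overlap, included Pde2a (-6.94 ± 1.11), Cyp4f18 (-5.17 ± 0.45), Neurl3 (-5.04 ± 0.36), the interleukin gene Il12a (-4.79 ± 0.68), Cpm (-4.59 ± 0.77), B3gnt8 (-4.31 ± 0.18), Nck2 (-4.28 ± 0.92) and Fam101b (-4.28 ± 0.78). Zbtb32 (chromosome 7, 30589680 to 30602819) rose by 7.16 ± 0.37, Myc rose by 1.82 ± 0.18 and Prdm1 by 3.08 ± 0.64, while Bcl6 fell by 3.53 and Bach2 fell by 1.29. Klf2 stood at 6.82 ± 0.77 and 7.87 ± 0.77 (adjusted p = 0.0975), and fell only with the replicate block (adjusted p = 0.000224). Of 13 B-1 and marginal zone genes 10 rose and 1 fell (10 and 2 with the replicate block, adjusted p = 9e-06), including Cd9 (6.05), Plscr1 (2.47) and Cd36 (4.50). Of 17 naive and quiescence genes 11 fell and 1 rose (adjusted p = 9.88e-05), including Cd55 (-2.73), Tsc22d3 (-3.39), Satb1 (-2.33) and Ccr7 (-1.77). Ribosome biogenesis and Myc targets rose in 13 of 20, including Ncl (2.66) and Npm1 (1.43; list adjusted p = 2.64e-05, and adjusted p = 0.0756 with an estimated correlation). MHC class II presentation fell in 9 and rose in 1 of 11 (10 fell adjusted over the list alone), including Ctss (-1.35) and H2-Oa (-1.66; list adjusted p = 0.000628, and adjusted p = 0.0881 with an estimated correlation). The median over all tested genes was -0.10.

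GL7 PreC cells differed from day 14 GC cells, LZ and DZ weighted equally, in 6695 genes, 3206 higher and 3489 lower. Higher in PreC, at a mean log2 value of at least 3 and without overlap, were Plac8 (10.25 ± 0.28 against 0.87 ± 0.48 in GC, n = 3 and 6, log2 fold change 9.38 ± 0.15), Pml (8.41 ± 0.26), Ly6d (8.12 ± 0.18), the chemokine receptor genes Ccr6 (7.62 ± 0.17), Cxcr3 (6.88 ± 0.51) and Ccr7 (6.88 ± 0.19), and S100a10 (7.18 ± 0.30). Lower in PreC were Basp1 (-9.68 ± 0.98), the growth hormone gene Gh (-8.91 ± 0.71), the lipase gene Lipc (-8.46 ± 0.37), Gcsam (-8.30 ± 0.66), Rgcc (-7.93 ± 1.11), Nuggc (-6.75 ± 0.63), Rgs13 (-5.95 ± 0.76) and Eaf2 (-5.69 ± 0.38). Of the 16 GC core genes, 15 were lower and 0 higher in PreC (adjusted p = 2.41e-08), with Bcl6 at -4.59 ± 0.21 and S1pr2 at -4.62. All but 1 of 15 sterol biosynthesis genes were lower (15 adjusted over the list alone, adjusted p = 8.03e-07), including Insig1 (-2.26), Sc4mol (-2.14), Cyp51 (-1.83) and Idi1 (-2.02). Of 16 memory-associated genes 14 were higher and 1 lower (adjusted p = 1.37e-08), including Cd38 (5.49) and Bcl2 (5.56). Type I interferon genes were higher in 13 of 18 (14 adjusted over the list alone, adjusted p = 3.69e-05), including Ifit2 (3.34) and Ifit3 (3.59). S phase genes went both ways, with 2 higher and 5 lower of 18 (1 and 4 adjusted over the list alone, adjusted p = 0.85), and Mki67 differed by -0.32 ± 1.04 (adjusted p = 0.814). Zbtb32 was higher in PreC by 4.61 ± 0.32, Myc by 1.99 ± 0.15, Klf2 by 5.41 ± 0.45 and Prdm1 by 3.81 ± 0.55, and Bach2 was lower (-2.38 ± 0.21).

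The 4 week 10 memory subsets together, against day 0 FO cells, had 1262 genes higher and 968 lower. With library quality weights these were 2380 and 2723, and without 1 FO library 1424 to 1558 genes passed in all. The memory libraries, taken as paired within each number, were counted as separate here. Higher in memory, at a mean log2 value of at least 3 and without overlap, were Serpine2 (7.54 ± 0.41), the ectonucleotidase gene Nt5e, which encodes CD73 (4.80 ± 0.56 against -2.20 ± 0.68, n = 12 and 3), Nrp2 (6.68 ± 0.49), the fatty acid receptor gene Ffar2 (5.89 ± 0.18), Ccbp2 (5.83 ± 0.27), Emb (5.58 ± 0.22), Lilrb4 (4.94 ± 0.38) and Cd59a (4.92 ± 0.20). Lower were the carbonic anhydrase gene Car2 (-4.19 ± 0.84), Sepp1 (-3.58 ± 0.25), Rgs18 (-3.05 ± 0.29), Cpm (-2.68 ± 0.61), Bcl6 (-2.25 ± 0.19), Vpreb3 (-2.22 ± 0.23), Crisp3 (-2.20 ± 0.61) and Dcaf12 (-2.14 ± 0.19). Of 13 B-1 and marginal zone genes 10 rose and 0 fell (adjusted p = 1.27e-12), including Cd9 (4.71), Myof (6.34) and S1pr3 (3.87). Of 17 naive and quiescence genes 11 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 6.94e-10), including Cd55 (-1.73), Fcer2a (-1.92), Btg2 (-1.03) and Tsc22d3 (-1.75). Age-associated and T-bet genes rose in 5 of 10 (6 adjusted over the list alone, adjusted p = 0.000299): Cd68 (3.96), Fcrl5 (4.51), Cxcr3 (4.18), Tlr7 (2.16) and Tbx21 (2.08). Among plasma cell genes 6 of 16 rose and 2 fell (adjusted p = 0.00627), including Derl3 (2.17), Prdm1 (3.69) and Mzb1 (0.57). Myc rose by 0.94 ± 0.14. Klf2 stood at 6.83 ± 0.71 and 7.87 ± 0.77 (adjusted p = 0.0795), and fell only with the replicate block (adjusted p = 4.46e-05). Day 0 FO replicate 1 carried Y-linked transcripts (Ddx3y 5.06, Eif2s3y 5.18) and Xist at -4.61, unlike the other FO libraries (Xist 4.99 and 5.56).

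GC cells against the week 10 memory subsets gave 3938 genes higher and 4251 lower. Birc5 (8.24 ± 0.27), the transcription factor gene Mef2b (8.22 ± 0.31), Rgs13 (7.90 ± 0.54), Ccnb2 (7.68 ± 0.52), Cdk1 (7.33 ± 0.23), Rrm2 (7.23 ± 0.25), Basp1 (7.22 ± 0.70) and Nusap1 (6.96 ± 0.25) were among the genes higher in GC. Tmem154 (-11.46 ± 0.35), the urokinase receptor gene Plaur (-10.84 ± 0.31), Serpine2 (-10.81 ± 0.32), Ccr1 (-10.72 ± 0.33), Ppap2b (-9.81 ± 0.30), Ly6d (-9.66 ± 0.13), Cd1d1 (-9.07 ± 0.24) and Entpd1 (-9.06 ± 0.38) were among those lower. All 16 GC core genes rose (adjusted p = 2.55e-10), as did all 20 G2/M genes (adjusted p = 2.74e-14), all 18 S phase genes (adjusted p = 5.2e-15) and all 15 sterol biosynthesis genes (adjusted p = 3.93e-08), the last including Idi1 (3.15), Cyp51 (2.30), Sqle (3.20) and Fdps (2.78). Oxidative phosphorylation genes rose in 16 and fell in 1 of 17 (adjusted p = 5.75e-06), including Atp5b (0.98). MHC class II presentation fell in 10 of 11 (adjusted p = 2.69e-05), including Ctss (-2.46) and H2-Oa (-2.05), and memory-associated genes in 12 of 16 (adjusted p = 6.48e-07), including Ccr6 (-6.93), Cd38 (-6.06), Hhex (-4.58) and Bcl2 (-5.99). Trafficking receptors fell in 12 of 16 and rose in 2 (adjusted p = 9.89e-06), including Ccr7 (-7.52) and Itgb7 (-5.29). Bcl6 was higher in GC by 3.31 ± 0.15 and Bach2 by 2.57 ± 0.15, and Prdm1 (-4.42 ± 0.39), Klf2 (-5.42 ± 0.32) and Myc (-1.11 ± 0.11) lower.

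At week 4 after FGK, 501 genes were higher and 779 lower in DP than in DN. Cd80 stood at 3.96 ± 0.24 in DP and -0.94 ± 1.57 in DN (n = 2 each), and Pdcd1lg2 at 6.46 ± 0.35 and 2.76 ± 0.16. Other increases were the actin-bundling gene Fscn1 (4.78 ± 0.67), Pdlim1 (3.84 ± 0.80), Gpr82 (3.63 ± 0.87), Dnase1l3 (3.19 ± 0.51), Zbtb20 (2.87 ± 0.46), Nid1 (2.86 ± 0.47) and Adm (2.85 ± 0.68). Decreases included the integrin gene Itgb3 (-4.74 ± 0.75), Cpm (-4.22 ± 0.94), Slc41a2 (-3.61 ± 0.31), Pdp1 (-3.21 ± 0.61), Neurl3 (-3.16 ± 0.44), Trib2 (-3.02 ± 0.34), Rgs18 (-2.94 ± 0.45) and the clock gene Cry1 (-2.85 ± 0.52). Zbtb32 rose by 4.63 ± 0.46, and Bcl6 fell by 1.89. The GC core list rose in 5 and fell in 2 of 16 (6 and 2 adjusted over the list alone, adjusted p = 0.0364, and adjusted p = 0.22 with an estimated correlation), with Neil1 (1.73) and Gcsam (5.33) up and Il21r (-1.96) down. Memory-associated genes rose in 5 and fell in 1 of 16 (6 and 1 adjusted over the list alone), including Itgb1 (0.91) and Nt5e (2.25; list adjusted p = 0.0272, and adjusted p = 0.22 with an estimated correlation). Naive and quiescence genes fell in 5 of 17 (6 fell and 1 rose adjusted over the list alone), including Cd55 (-1.10), Satb1 (-2.11), Fcer2a (-0.98) and Foxo1 (-1.39; list adjusted p = 0.00982, and adjusted p = 0.22 with an estimated correlation). The DP libraries had 10056 and 11016 genes above their lowest value against 10785 and 11877 in DN, and the myeloid gene Lyz2 stood at 4.16 and 2.91 against 5.50 and 6.38, while the myeloid gene Mpo stood at 9.48 and 4.06 against 6.40 and -3.49. A fit of only these 4 libraries called 4 genes, library quality weights 260, and leaving out 1 library gave 477 (DN replicate 1) and 623 (DP replicate 1).

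After NP-Ficoll, DP had 31 genes higher and 27 lower than DN at week 4. Cd80 stood at 2.62 ± 0.74 in DP and -0.97 ± 0.46 in DN (n = 2 each), and Pdcd1lg2 at 5.60 ± 0.27 and 2.95 ± 0.43. Fah, an enzyme of tyrosine breakdown (1.91 ± 0.26), Ntpcr (1.04 ± 0.24), Atmin (1.04 ± 0.24), Slamf7 (1.03 ± 0.22), the DNA repair gene Neil1 (0.99 ± 0.21) and St3gal6 (0.88 ± 0.21) rose. Rgs18 (-2.84 ± 0.45), Trib2 (-1.85 ± 0.34), Lpar6 (-1.46 ± 0.33), Slc16a6 (-1.17 ± 0.28), the costimulatory ligand gene Icosl (-1.11 ± 0.20), Ube2l6 (-1.11 ± 0.25), Tmed9 (-1.06 ± 0.21) and Gimap8 (-1.05 ± 0.18) fell. Bcl6 fell by 1.61 and Zbtb32 differed by 0.83 ± 0.46 (adjusted p = 0.69). Light zone genes went both ways, with Cd86 up (0.70) and Icosl and Slamf1 (-1.54) down and 3 and 2 adjusted over the list alone (list adjusted p = 0.913). Naive and quiescence genes had a median of -0.32 and 1 member past the threshold, Cd55 (-0.74; list adjusted p = 0.0227, and adjusted p = 0.513 with an estimated correlation). Myeloid markers had a median of -2.31 with 0 of 13 past the threshold (list adjusted p = 0.0227, and adjusted p = 0.513 with an estimated correlation). Lyz2 stood at 7.69 and 7.47 in DN and at 4.21 and 7.59 in DP. With a myeloid marker covariate 25 genes passed, a fit of only the 4 libraries gave 12, library quality weights gave 138 (63 higher, 75 lower), and leaving out 1 library gave 2 and 19 (DN replicates 1 and 2) and 26 (DP replicate 1).

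Week 4 libraries carry FGK or NPFic in place of NPCGG and were deposited apart from the week 10 DN and DP libraries. Time, condition label and deposition thus change together. Genes called in week 10 DP versus DN were looked up at week 4. Of the 311, 248 (79.7%) had the same sign after FGK and 226 (72.7%) after NP-Ficoll. Called in both with the same sign were 80 higher and 49 lower genes for FGK, where 8.1 and 7.8 would overlap between independent lists, and 9 and 7 for NP-Ficoll, where 0.5 and 0.3 would. Called with opposite signs were 4 genes for FGK and 1 for NP-Ficoll. With library quality weights 47 higher and 52 lower genes were shared for FGK and 23 and 17 for NP-Ficoll, and 6 had opposite signs in each. The shared higher genes include Cd80 and Pdcd1lg2, whose difference follows from the sort. The genes called with the same sign in all 3 settings included Cd80, Pdcd1lg2, Fscn1, Cd86, Morn1, Fah, Neil1 and Syngr2 (higher in DP) and Rgs18, Lpar6, Bcl6, Dhx40, Cd55, Icosl and Cd84 (lower). Across all tested genes, which are not independent replicates, the fold changes of week 10 and week 4 correlated at Pearson r = 0.30 for FGK and 0.19 for NP-Ficoll (Spearman 0.17 for both).

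CD80SP and DN cells at week 4, the conditions weighted equally, differed in 137 genes, 65 higher and 72 lower. Cd80 was higher by 3.83 ± 0.51 and Pdcd1lg2 differed by -0.32 ± 0.30, which did not pass. Fah (1.44 ± 0.19), Ccbp2 (1.43 ± 0.30), the dynein gene Dync1h1 (1.12 ± 0.24), Pde3b (0.90 ± 0.23) and Tln1 (0.83 ± 0.20) rose, and Neurl3 (-2.21 ± 0.31), Vpreb3 (-1.64 ± 0.25), Ube2l6 (-0.99 ± 0.18), Bnip3 (-0.78 ± 0.19) and Cytip (-0.72 ± 0.11) fell. Zbtb32 (1.69 ± 0.32) and Myc (0.64 ± 0.15) rose. The B-1 and marginal zone list moved up with 1 of 13 past the threshold (Zbtb32) and 2 adjusted over the list alone (adjusted p = 0.0025). The T cell marker list moved down (median -1.01; adjusted p = 0.0025, and adjusted p = 0.304 with an estimated correlation), with Lck at -0.65 and 3 fallen adjusted over the list alone. The myeloid gene Lyz2 stood at 4.78 and 4.53 (FGK) and at -0.34 and 7.14 (NPFic) in CD80SP. In DN it stood at 5.50 and 6.38 (FGK) and at 7.69 and 7.47 (NPFic). The count was 47 with a myeloid marker covariate and 91 with library quality weights, and median centring gave 62 higher and 47 lower. Without 1 library it was 31 and 409 (CD80SP NPFic replicates 1 and 2), 55 and 66 (DN NPFic replicates 1 and 2), 66 and 258 (DN FGK replicates 1 and 2) and 67 (CD80SP FGK replicate 1).

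NP-Ficoll against FGK, the 3 week 4 subsets weighted equally, gave 1423 genes higher and 1116 lower. With a myeloid marker covariate these were 1023 and 867. The myeloid gene Lyz2 ranged from -0.34 to 7.69 over the NP-Ficoll libraries and from 2.91 to 6.38 over the FGK libraries. The tetraspanin gene Cd9 stood at 7.87 ± 0.47 after NP-Ficoll and 5.19 ± 0.52 after FGK (n = 6 each; log2 fold change 2.68 ± 0.21). Hepacam2 (2.19 ± 0.44), Cd68 (2.16 ± 0.34), Creb3l2 (2.09 ± 0.38), Epcam (1.93 ± 0.45), Kcnn4 (1.92 ± 0.13), Homer1 (1.84 ± 0.26) and the glucocorticoid-induced gene Tsc22d3 (1.81 ± 0.20) were also higher. Asb2 (-3.64 ± 0.37), the T-bet gene Tbx21 (-3.38 ± 0.35), Cnn3 (-3.18 ± 0.24), Sema5a (-2.83 ± 0.36), Akap2 (-2.36 ± 0.17), the cytokine receptor gene Il9r (-2.32 ± 0.19), Morn1 (-2.24 ± 0.18) and Chst10 (-2.19 ± 0.16) were lower. GC core genes fell in 5 and rose in 1 of 16, with Bcl6 (-2.06) and the death receptor gene Fas (-2.09) down (list adjusted p = 0.00487, and adjusted p = 0.0543 with an estimated correlation). Light zone genes fell in 8 and rose in 2 of 19 (10 and 3 adjusted over the list alone), including Slamf1 (-3.02), Icosl (-1.63) and Fcer2a (-1.47; list adjusted p = 6.7e-05). G2/M genes rose in 11 of 20, including Ccnb1 (1.87), Ccna2 (2.07) and Kif11 (3.44; list adjusted p = 7.2e-06, and adjusted p = 0.0543 with an estimated correlation). Plasma cell genes rose in 7 of 16, including Edem1 (1.51), Mzb1 (0.45), Tnfrsf17 (3.57) and Creld2 (0.42; list adjusted p = 0.000907). Zbtb32 rose by 1.97 ± 0.26. T cell markers rose in 6 of 8, including Cd3e (6.90), Cd3d (3.92) and Lck (1.07; list adjusted p = 2.91e-06). Thy1 and Cd8a of that list stayed below 0 in every library and were left out by the filter on low values. Cd3e passed the filter through the NP-Ficoll libraries, since its highest value elsewhere was 0.29. The count and the list p thus lean toward genes detected after NP-Ficoll. Myeloid markers rose in 3 of 13, Csf1r (3.49), C1qb (3.71) and C1qa (3.03; list adjusted p = 0.0256, and adjusted p = 0.364 with an estimated correlation).

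**Figure D2:**
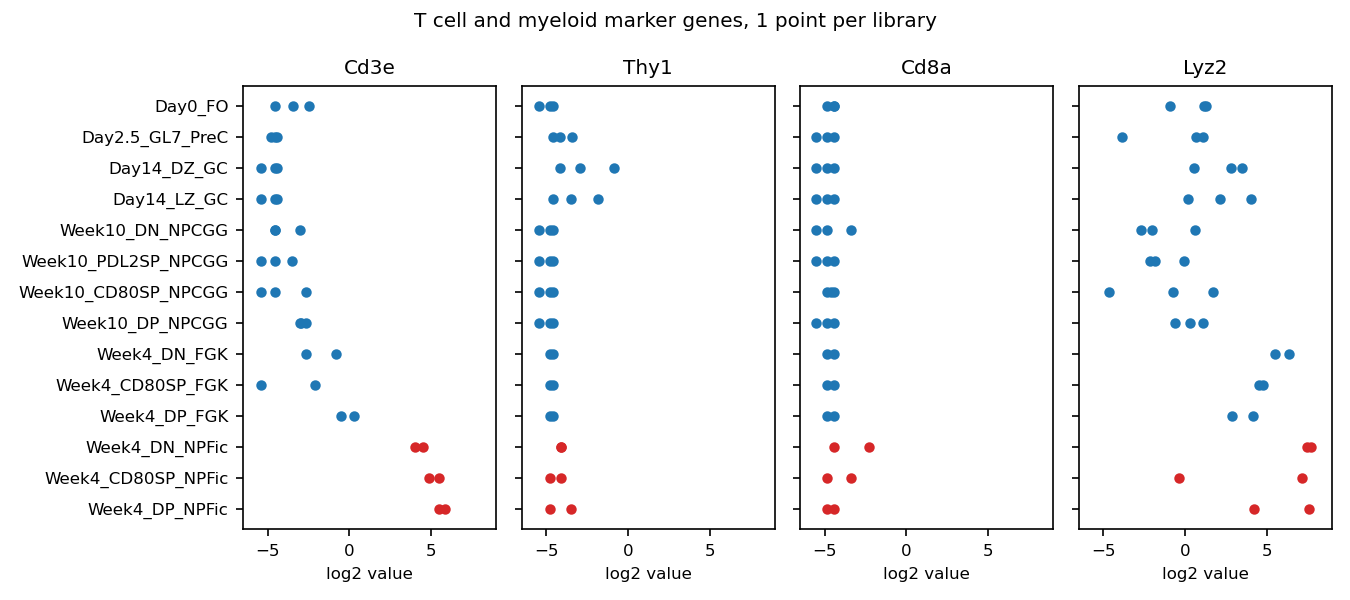
Log2 values (x axis) of the T cell genes Cd3e, Thy1 and Cd8a and the myeloid gene Lyz2, 1 point per library, by group (y axis); NPFic groups are in red. Cd3e lies between 4.04 and 5.86 in the 6 NPFic libraries and at 0.29 or below in the other 30.

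To place the putative precursors among known subsets, 2 scores were computed. The DP-DN signature score (148 genes higher and 72 lower in week 10 DP) was -3.46 ± 0.06 in FO and -0.84 ± 0.15 in GL7 PreC cells (n = 3 each), a difference of 2.62 (exact permutation p = 0.1, the smallest that 3 against 3 allows). All PreC libraries lay above all FO libraries. PDL2SP stood at -1.76 ± 0.18 and CD80SP at -0.25 ± 0.19, between DN (-3.56 ± 0.31) and DP (1.58 ± 0.19), which define the score; CD80SP and PDL2SP differed by 1.51 (exact permutation p = 0.1). DZ and LZ cells stood at 2.24 ± 0.17 and 2.15 ± 0.18. At week 4, DN, CD80SP and DP stood at -3.91 ± 0.20, -2.02 ± 0.01 and -0.67 ± 0.32 after FGK, and at -1.91 ± 0.05, -1.17 ± 0.31 and -0.58 ± 0.27 after NP-Ficoll (n = 2 each). On the GC-memory signature score (2016 genes higher and 2279 lower in GC), PreC stood at -0.35 ± 0.06 and FO at -1.89 ± 0.11 (difference 1.55, exact permutation p = 0.1), and the difference was 3.14 with the 100 genes of smallest p in each direction. The defining groups lay at 2.94 ± 0.29 (DZ) and 2.39 ± 0.41 (LZ), and between -2.63 ± 0.12 (DN) and -2.35 ± 0.14 (DP). All week 4 groups lay between -2.37 ± 0.01 and -2.08 ± 0.03. Adjusted over the 3 score comparisons, each p stayed at 0.1.

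**Figure D3:**
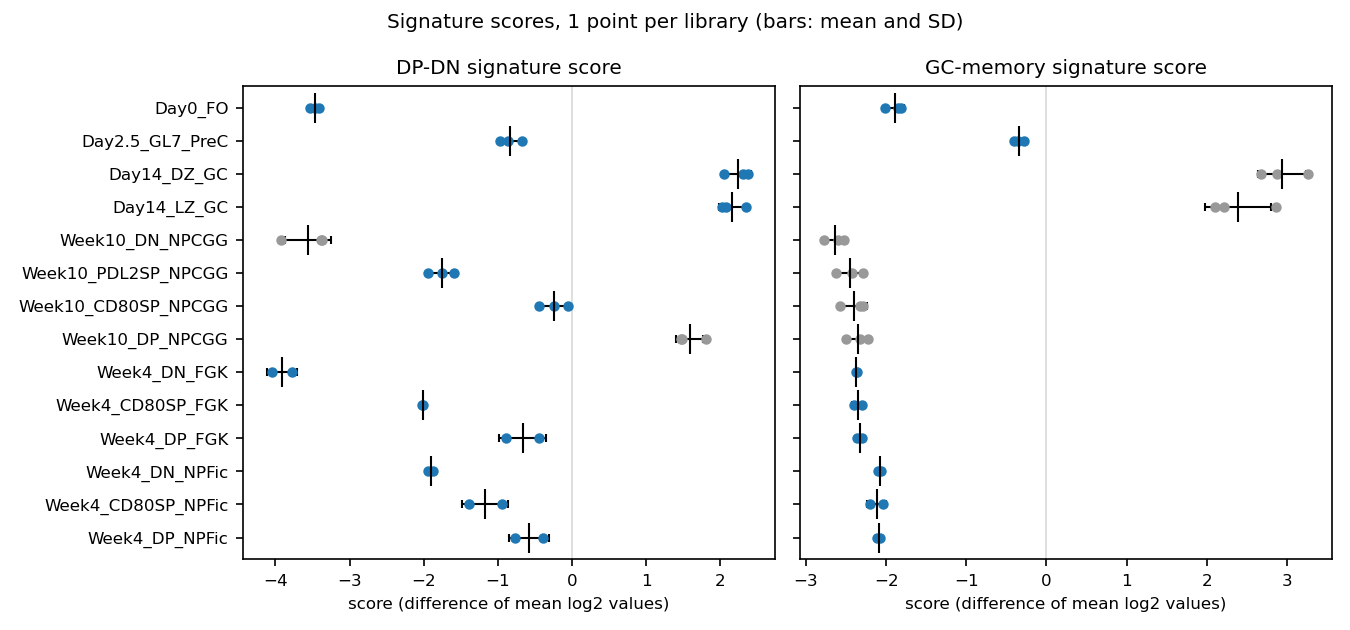
DP-DN score (left) and GC-memory score (right) of each library (points; x axis, difference of mean log2 values) by group (y axis), with mean and SD; groups that define a score are grey. GL7 PreC libraries lie at -0.84 ± 0.15 and -0.35 ± 0.06, above FO on both scores.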

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

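Of the tests in this part, those on splits of the libraries were chosen after the split counts had been seen. The tests of Cd3e and of the FGK counts were written before their values were seen, the last (spread) after related counts were known.

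The DP versus DN difference at week 4 differed between NP-Ficoll and FGK in 125 genes by the interaction term (limma, adjusted p under 0.05). Those named by the rule were Nab1 (2.06 on the log2 scale, NP-Ficoll minus FGK), Bad (1.42), Fyttd1 (0.88), Itga4 (-1.45), Odf2 (-1.33) and Ndel1 (-0.72). Zbtb32 also differed, by -3.79 ± 0.65 (SE). Cd80 (-1.31 ± 1.02) did not pass. The count was 9 with library quality weights and, without 1 library, 51 and 451 (DN FGK replicates 1 and 2), 827 (DP FGK replicate 2), 44 and 76 (DN NPFic replicates 1 and 2) and 80 and 67 (DP NPFic replicates 1 and 2).

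In the pooled model DP versus DN called 1280 genes after FGK and 58 after NP-Ficoll, but fits of only the libraries compared called 4 and 12, so that the order turned, and quality weights gave 260 and 138. Lower gene detection in the FGK DP libraries is argued against as the whole source of the pooled counts only: among genes with a mean log2 value of at least 5, FGK still gave 431 genes and NP-Ficoll 16, a ratio of 26.9, where under 3 had been set as its mark. A wider spread between FGK libraries stays open, since their median within-group SD was 1.44 times that of the NP-Ficoll libraries, between the bounds of 1.1 and 1.5 set beforehand. A larger difference after FGK, the biological alternative, stays open too, since the interaction term, which tests it, called 125 genes in the pooled model and 4 in a fit of only these libraries.

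Cd3e, which encodes a chain of the T cell receptor complex, stood at 5.04 ± 0.69 (SD, n = 6) in NP-Ficoll libraries and -1.86 ± 2.03 (n = 6) in FGK libraries. RNA of T cells would bring other T cell transcripts. The 12 further T cell genes tested differed by a median of 1.01 (quartiles 0.20 and 2.03), so Cd3e exceeded that median by 5.9. More than 4 had been set as evidence against T cells as the whole source, and 5 of the 12 stayed below 0 in every NP-Ficoll library. How abundant the 12 are in T cells was not measured here. Among them Cd2, at 7.61 after NP-Ficoll, differed by -0.03, so it was high after FGK too. Expression of Cd3e by the NP-Ficoll B cells, or an effect of the sort or reagents shared by those libraries, stays open as a hypothesis, and neither was tested. Cd3g (3.45), Cd3d (3.92), Il7r (3.67) and Cd247 (2.56) of the fixed list rose too, and the libraries were sorted, by gates the labels do not describe.

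Other splits of the libraries gave fewer genes than the real one for NP-Ficoll versus FGK (2539 against at most 973, 1 of 100 splits as large). Chance can be excluded there only if these libraries are independent, which the labels do not say. Splits also gave fewer genes for memory versus FO (2230 against 1248, 1 of 100). Memory and FO libraries were taken as paired by number from their values alone. Splits within each number gave at most 453 genes (1 of 100 as large). Fewer genes also came from splits for PreC versus GC (6695 against 4692, 1 of 84) and GC versus memory (8189 against 5423, 1 of 100). For memory versus FO, PreC versus GC and GC versus memory, the splits treat paired GC or paired memory libraries as separate, so chance is left open. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count and the highest other were 311 and 0 for DP versus DN, 2 and 1 for PDL2SP versus DN, 269 and 0 for CD80SP versus DN, 113 and 0 for DP versus PDL2SP, 190 and 0 for DP versus CD80SP, and 5838 and 0 for PreC versus FO, with 1 split as large each. For CD80SP versus PDL2SP (56 against 2219) and LZ versus DZ (487 against 816), 2 splits were as large. Each of those highest splits parted 1 of the 3 same-number pairs; the count of 2219 points to a structure of the libraries, whose source was not tested. The 3 other splits that part all 3 pairs, as the real one does, gave at most 0 and 4 genes, and the blocked counts were 86 and 687. For week 4 CD80SP versus DN (137), 9 of 35 splits were as large, so chance cannot be excluded this way; the highest, 1408, parts FGK from NP-Ficoll.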

How the results depend on the processing

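Pseudocounts, median centring, quality weights, the omission of all libraries numbered 3 and the myeloid covariate were chosen after the data were seen; the cause of a moved value was not tested unless fewer libraries explain it. Over all settings, the 210 named genes that passed gave 2987 outcomes on the same side of the threshold, 399 weaker and 0 reversed. Apart from the label genes, they were chosen for having no overlap between the sides. A reversal was therefore largely ruled out in advance, and its absence says little. Depth is unknown, so what it limits could not be measured. RLE size factors, DESeq2 and voom weights need counts, and the fit without immunoglobulin genes and the scores' prior count had nothing to act on, so these were not run.

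With the replicate block, the counts were 4 for PDL2SP versus DN, 1348 for CD80SP versus DN, 200 for DP versus PDL2SP, 1098 for DP versus CD80SP and 86 for CD80SP versus PDL2SP; the other counts stayed within 1.5 times. Of the named genes 207 kept their call with the block, and Bhlhe41 (CD80SP versus PDL2SP), St3gal6 (NPFic DP versus DN) and Odf2 (interaction) lost it. Klf2 passed only with the block in PreC versus FO and in memory versus FO, as did Bcl6 in CD80SP versus PDL2SP (adjusted p = 0.0287); no other gene or list call given above changed. At week 4 same-number libraries correlated at -0.031 to 0.006 (FGK) and -0.055 to 0.335 (NPFic), and 22 of 30 libraries correlated best with their own number.

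In fits of only the libraries compared, the counts were 74 (CD80SP versus DN), 50 (DP versus PDL2SP), 27 (DP versus CD80SP), 5 (CD80SP versus PDL2SP), 61 (LZ versus DZ), 4 (FGK), 12 (NPFic) and 4 (interaction), with fewer libraries to estimate the spread. With no filter on low values PDL2SP versus DN gave 5 and NPFic 155, and the stricter filter gave 70 for the interaction. A pseudocount of 1 gave 9 (PDL2SP versus DN), 202 (DP versus PDL2SP), 320 (DP versus CD80SP), 106 (CD80SP versus PDL2SP) and 124 (NPFic). Quality weights gave 1143 (DP versus DN), 246 (PDL2SP versus DN), 4133 (CD80SP versus DN), 1354 (DP versus PDL2SP), 3812 (DP versus CD80SP), 3236 (CD80SP versus PDL2SP), 5103 (memory versus FO), 260 (FGK), 138 (NPFic), 91 (week 4 CD80SP versus DN) and 9 (interaction), and 74.0% same-sign genes for FGK. Without all libraries numbered 3 the counts were 122 (DP versus DN), 1 (PDL2SP versus DN), 42 (DP versus PDL2SP) and 8 (CD80SP versus PDL2SP). The myeloid covariate gave 25 (NPFic) and 47 (week 4 CD80SP versus DN). With an estimated correlation 61 of 138 list calls passed. A pseudocount of 0.5 gave score differences of 1.86 and 1.28 (PreC minus FO, DP-DN and GC-memory) and 1.03 (CD80SP minus PDL2SP), and the 100 genes of smallest p gave 3.14 for the GC-memory signature score.

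Leaving out 1 library gave score differences of 2.31 to 3.16 and 1.53 to 1.64 (PreC minus FO, DP-DN and GC-memory) and 1.43 to 1.59 (CD80SP minus PDL2SP). Counts ranged from 180 to 220 (DP versus DN, against 311 with all libraries), 0 to 2 (PDL2SP versus DN), 68 to 1202 (CD80SP versus DN), 65 to 119 (DP versus PDL2SP), 22 to 865 (DP versus CD80SP), 25 to 98 (CD80SP versus PDL2SP), 318 to 659 (LZ versus DZ), 5078 to 5271 (PreC versus FO), 5705 to 6600 (PreC versus GC), 1424 to 2454 (memory versus FO), 7778 to 8244 (GC versus memory), 477 to 1902 (FGK), 2 to 53 (NPFic), 31 to 409 (week 4 CD80SP versus DN), 2005 to 2760 (NPFic versus FGK) and 44 to 827 (interaction). Where 1 library was left in a group it was assumed to vary like the others.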

Other observations

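The test of replicate numbers in this part was written before its value was seen, but a version narrower than the one written was run first. The values in the next 2 paragraphs were picked after they were seen.

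Gh, the growth hormone gene, stood at 6.15 ± 0.34 in DZ and 5.90 ± 0.23 in LZ cells (n = 3 each), against 1.98 ± 0.67 in FO and -2.88 ± 0.61 in GL7 PreC cells. From FO to GL7 PreC cells the age-associated and T-bet list rose in 7 of 10 genes (8 adjusted over the list alone, camera adjusted p = 0.000427), including Cxcr3 (6.15), Cd68 (6.46), Itgax (6.64) and Fcrl5 (3.95). Glycolysis genes rose in 10 and fell in 1 of 15 from FO to PreC (10 and 2 adjusted over the list alone), including Ldha (1.55), Gapdh (1.67), Tpi1 (1.72) and Pkm (1.62; list adjusted p = 9.74e-05, and adjusted p = 0.064 with an estimated correlation). The chaperone genes Hsp90b1 (3.51) and Pdia4 (3.80) of the unfolded protein response list were higher in PreC than in GC cells (8 of 14 rose and 3 fell; list adjusted p = 0.0279, and adjusted p = 0.292 with an estimated correlation).

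Y-linked Ddx3y stood at 5.06 in day 0 FO replicate 1, at 1.12 in week 4 DN NPFic replicate 2 and at 1.74 in week 4 DP NPFic replicate 2. Xist stood at 6.82 and 6.55 in those NP-Ficoll libraries. Eif2s3y, also Y-linked, stood at 2.50 and -0.85 in DN NPFic replicates 1 and 2. It stood at 0.48 in CD80SP NPFic replicate 2 and 1.75 in DP NPFic replicate 2, against -4.12 in replicate 1 of each. Lyz2 stood above 7 in 4 of the 6 NP-Ficoll libraries (7.69 and 7.47 in DN, 7.14 in CD80SP replicate 2 and 7.59 in DP replicate 2). In the libraries with Eif2s3y at -4.12 it stood at -0.34 (CD80SP replicate 1) and 4.21 (DP replicate 1). Ddx3y lay above its lowest value for replicate 1 (-4.0) in these libraries too, at -1.24 and -2.71. It lay above its lowest value in all 6 NP-Ficoll libraries.

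Libraries numbered 3 lay nearer to week 4 libraries, which have no number 3, than libraries numbered 2 did: across tested genes, number 3 minus number 2 correlated with week 4 minus the other libraries numbered 1 at Pearson r = 0.56, and above 0 in each of 8 groups (0.11 to 0.51). A candidate explanation is the adjustment by replicate number, made without allowing for the groups in each number; another is a shared biological or handling difference of the third replicates. The test correlated, across 11725 genes of which 5810 do not vary, the shift of the lowest value in number 3 with the week 4 difference and gave r = 0.06, below the 0.1 set as evidence against the adjustment. A narrower version that was run first, on 564 tested genes and against number 1 only, gave 0.19, between the bounds of 0.1 and 0.3. Libraries numbered 3 on the other side lower the first value and number 1 on both sides raises the second, so the explanations cannot be told apart here.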
